A study of Bos taurus with 6 samples.

How the data were processed

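The series holds 6 two-colour microarrays of bovine granulosa cells, on Agilent slides with 43794 gene probes among 45220 spots. Per the labels' protocols, total RNA was extracted with the PicoPure kit, amplified to antisense RNA over several rounds with the RiboAmp HSPlus kit, and labelled with Cy3 and Cy5 by the ULS chemistry of Kreatech. Amplification from very little RNA can compress or distort ratios, and such an effect would be shared by both arrays of a dye-swap pair.

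The deposited scanner files give, per the file headers, the median pixel intensity of each spot in the green (Cy3) and red (Cy5) channels and the median intensity of the local background. The scanner and the image analysis program are not given in the sources used here. The authors also deposited a table of log2 ratios of the same arrays, whose making is not given in the sources used here. Set against the turned log2 ratios computed from the scanner files, its columns had r = 0.962, 0.95, 0.948, 0.931, 0.879 and 0.861 for arrays 1 to 6, so all run as vitamins over saline, and slopes from 0.71 to 0.98. Their medians were 0.001, 0.015, -0.018, -0.007, -0.003 and 0.005. The background correction, the normalization and any shrinkage behind that table stay unknown, and it was used only as an alternative.

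Groups were taken from the labels, which state the treatment of each channel: on 3 arrays vitamins were in Cy5, on 3 arrays in Cy3. The series design states 3 biological replicates with 2 dye-swapped technical arrays each, but the labels do not say which arrays form a pair. The pairing was therefore taken, by a rule fixed before the data were examined, as the matching of opposite orientations with the highest summed correlation of ratios after centring within each orientation. It was arrays 1 and 2, 3 and 4, and 5 and 6, with a sum of 2.46 against 0.731 for the next matching. Arrays 1 and 2 lie on one slide and the other 4 on another. The pairing does not change a mean ratio, only its spread.

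Analysis used R 4.3.3 and limma 3.58.1. Intensities were background-corrected with normexp (offset 50) over all spots and normalized within arrays by loess with control spots at weight 0. Spots that the image analysis marked as ignored (2 to 71 per array) were left out, and control spots after normalization. Saturated spots, at most 27 gene probes in a channel, were kept. A reading was detected when its signal exceeded the mean plus 2 SD of the 153 negative-control spots of its array and channel. Detection ranged from 23269 to 30104 probes per channel, and 14893 probes were detected in all 12 readings. A probe was tested when detected in at least 6 of 12 readings, which left 26714, of which 1 had no value in a replicate. No named gene was undetected in all 6 readings of a group, so no fold is given as a bound.

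Each array's log2 ratio was turned to vitamins over saline, and both arrays of a pair were averaged. The 3 replicate ratios were tested against 0 with lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment over all probes and a threshold of 0.05. The dye effect cancels in the mean of a pair. Where a spot was ignored on an array of a pair, the other array alone gave the value, and the dye effect stays in it. Errors are SDs of the 3 replicate ratios. For a gene with several probes, the brightest tested probe gives the value, and the range over its probes is stated where they disagree.

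The platform annotation gives 1 gene symbol for 21790 probes, several for 0 and none for 22004. Of the named probes, 20025 had a symbol current in the RefSeq gene table (assembly ARS-UCD2.0) and 1524 were updated through a unique synonym; others keep the older symbol. No genome was used and no coordinates are given.

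The 31 gene lists were fixed before the data were examined and tested with camera on 1 probe per gene (10946 genes), with an inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. camera sets a list's genes against all other genes. fry asks whether a list's genes move on balance one way, without that comparison. All lists had at least 5 measured genes. Genes share lists: CYP19A1 belongs to 2 of the lists that passed, and so do RRM2, HSD17B1 and NR5A2. Genes were named by a rule fixed at the same time: among genes past the threshold, the 10 largest rises and falls with 1 sign in all 3 replicates and in both dye orientations; where fewer passed, the smallest unadjusted p with an absolute log2 ratio of at least 0.58, up to 8 per direction; the 2 members of lowest unadjusted p in each list; and 14 genes in every case (FSHR, LHCGR, CYP19A1, STAR, CYP11A1, HSD3B1, MTR, MTRR, DNMT1, AREG, PTGS2, PGR, VEGFA and 1 that is not reported here).

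The steps were tested on simulated data with the variance of the 26713 tested probes, 200 of them changed. For the comparison of vitamins with saline, the adjusted test recovered 0% of probes changed by 1 on the log2 scale, 44% at 2, 56% at 3 and 82% at 4, with 2 unchanged probes called. For the list tests, a list of 25 genes shifted by -1 was called in 20 of 20 draws with the preset correlation and in 0 of 20 with an estimated correlation, and 0 of 600 unshifted lists were called. The simulated genes varied independently, which real genes do not.

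Alternatives covered the background correction, the normalization, the filter on dim probes, the pairing, a model of the 6 arrays with a dye term, the slide as a block and each slide alone, an intensity trend, each replicate left out, the authors' deposited log2 table, the mean of a gene's probes, an estimated correlation and fry. The closing section gives their effect.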

Results

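Gene expression was measured in granulosa cells of dairy cows after calving. Granulosa cells line the ovarian follicle, make estradiol from androgen and nurse the oocyte. Treated cows had received intramuscular folic acid (320 mg) with vitamin B12 (10 mg), and control cows 0.9% saline, from 3 weeks before calving to day 57 ± 2 after it. Both vitamins serve the transfer of one-carbon units, which feeds the synthesis of nucleotides and the methylation cycle. The cells were aspirated 66 ± 2 h after a second dose of prostaglandin F2 alpha, from preovulatory follicles of at least 12 mm. Collection fell on day 57 or, where no such follicle was present, on day 71. Each of the 6 arrays carried RNA from vitamin-treated cows in one dye and RNA from saline-treated cows in the other. Vitamins were in Cy5 on 3 arrays and in Cy3 on 3 arrays. The series design describes 3 biological replicates with 2 dye-swapped arrays each, so the values below rest on 3 replicate ratios. The labels do not say whether a replicate is a single cow or a pool. The p-values of single genes rest only on the spread between the 3 ratios of each probe, moderated by eBayes towards that of all probes. Those of the list test with a preset correlation set a list's genes against all other genes. They rest on the spread across genes, not directly on that between replicates. Between 53.1% and 68.7% of the 43794 gene probes were above the negative controls in a channel, and 26713 probes, covering 10946 named genes, were tested. The number of arrays limits the precision.

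The comparison asks how the vitamins changed gene expression in granulosa cells of the preovulatory follicle. The list of cell cycle genes had a median log2 ratio over 38 genes of -1.21 with vitamins, a 2.31-fold lower level, and its median was below 0 in all 3 replicates. Genes of nucleotide synthesis had a median of -0.30 over 20 genes, with -0.72, -0.34 and 0.06 in replicates 1, 2 and 3. Genes of the extracellular matrix and basal lamina had a median of 0.33 over 22 genes, above 0 in all 3 replicates, though 6 of the genes were above 0 in each of them, and genes of steroid synthesis had a median of 0.20 over 20 genes (0.21, 0.28 and 0.02 in replicates 1, 2 and 3). Genes of the estrogen-active dominant follicle had a median of 0.19 over 25 genes, with 0.65, -0.11 and 0.11 in the 3 replicates. These are the 5 of 31 gene lists that passed limma's camera test with a preset correlation between genes. None of them passed with an estimated correlation (adjusted p = 0.767 for each, the lowest of any list). That setting could not decide here, as it called a simulated list shifted by -1 in 0 of 20 draws, though the simulated genes varied independently. No single gene passed the test across all probes.

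**Figure D1:**
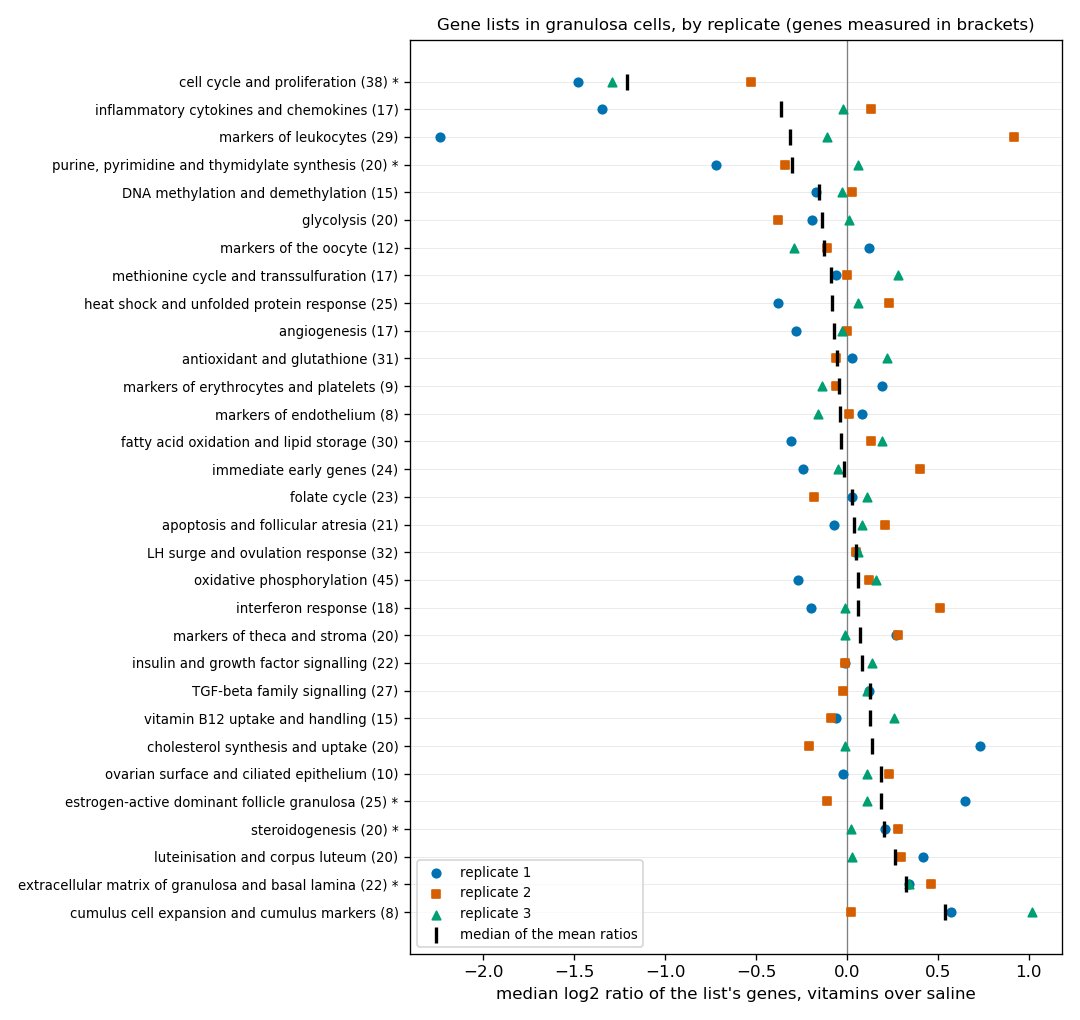
Median log2 ratio, vitamins over saline, of the genes of each list (x axis) for the 31 lists (y axis, number of genes measured in brackets); circles, squares and triangles are the 3 replicates, the black bar is the median of the genes' mean ratios, and an asterisk marks the 5 lists past the threshold with a preset correlation. The cell cycle list lies at -1.48, -0.53 and -1.29 in the 3 replicates, while the leukocyte markers lie at -2.24, 0.92 and -0.11.

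Of the 38 cell cycle genes measured, 36 had a mean log2 ratio below 0 and 30 were below 0 in each of the 3 replicates; none was above 0 in all of them. KIF11, a mitotic kinesin, had a log2 ratio of -1.75 ± 0.31 (SD, n = 3). PCNA, the sliding clamp of DNA replication, was at -1.55 ± 0.39 (SD, n = 3), with its 4 probes between -1.55 and -1.03. CCNB1, the cyclin of entry into mitosis, stood at -2.36 ± 1.14 (SD, n = 3) and AURKB, a mitotic kinase, at -1.60 ± 0.61 (SD, n = 3), with its 3 probes between -1.60 and -0.17; these 2 genes were chosen after their values were seen. Adjusted over the list alone, 24 genes were lower and 0 higher, and 0 passed over all probes tested. The list fell by limma's camera (adjusted p = 6.2e-26, lower in 3 of 3 replicates); adjusted p = 0.767 with an estimated correlation, and the alternatives ranged from 2.58e-31 to 0.767. The estimated correlation between the list's genes was 0.341, above the preset value. The adjusted p of 6.2e-26 by camera thus treats these genes as nearer to independent than that estimate. The list's median was -1.05 on the arrays with vitamins in Cy5 and -1.21 on those with vitamins in Cy3. Replicate 1 was hybridised on a slide of its own and replicates 2 and 3 on another. The median was -1.48 on the first slide, -0.93 on the second, and -1.26 with the slide as a block. The replicate medians were -1.48, -0.53 and -1.29, where those of the leukocyte markers were -2.24, 0.92 and -0.11.

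In the list of purine, pyrimidine and thymidylate synthesis, 17 of 20 measured genes were below 0, and 5 were below 0 in every replicate. Thymidylate synthase (TYMS), which uses a folate to make the thymine of DNA, had a log2 ratio of -1.03 ± 0.27 (SD, n = 3), but its 3 probes ran from -1.03 to 0.12. RRM2, a subunit of ribonucleotide reductase that is also a member of the cell cycle list, was at -1.21 ± 0.31 (SD, n = 3; 3 probes between -2.10 and -0.84), with -1.64 where vitamins were in Cy5 and -0.79 where they were in Cy3. These 2 genes were the ones that passed adjusted over the list alone, and 0 passed over all probes. The list fell by camera (adjusted p = 0.00635, median below 0 in 2 of 3 replicates); adjusted p = 0.767 with an estimated correlation, and the alternatives ranged from 0.000143 to 0.89. Without the shared gene, an alternative chosen after seeing the data, the adjusted p was 0.0283 over 19 genes. Genes of DNA synthesis such as TYMS stay in the list, so this cannot separate it from the cell cycle genes. The medians were -0.72, -0.34 and 0.06 in replicates 1, 2 and 3. On the slide of replicates 2 and 3 alone the median was -0.22 (adjusted p = 0.30), without replicate 2 it was -0.23 (0.0604) and without replicate 3 it was -0.57 (0.000143). With the slide as a block the median was -0.31.

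Of the 22 genes of the granulosa extracellular matrix and basal lamina, 20 had a mean above 0 and 6 were above 0 in all 3 replicates. The members of lowest unadjusted p were COL4A5 (0.64 ± 0.12, SD, n = 3) and COL4A2 (1.07 ± 0.68, SD, n = 3). These are chains of type IV collagen, the network-forming collagen of basement membranes. They were picked by their p, so they do not stand for that collagen as a whole, and any other measured chains are not given here. Adjusted over the list alone 0 genes passed, as over all probes. The list rose by camera (adjusted p = 0.00117, higher in 3 of 3 replicates); adjusted p = 0.767 with an estimated correlation, and the alternatives ranged from 0.000203 to 0.767. Its medians were 0.34, 0.46 and 0.34 in the 3 replicates, so 0.34 on the slide of replicate 1. The list's median was 0.32 on the slide of the others and 0.28 with the slide as a block. The median was 0.22 with median centring in place of loess.

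Among 25 measured genes of the estrogen-active dominant follicle, 18 had a mean above 0 and 8 were above 0 in all 3 replicates. Aromatase (CYP19A1), which converts androgen to estradiol, had a log2 ratio of 2.21 ± 1.34 (SD, n = 3), with 3.59, 2.12 and 0.92 in replicates 1, 2 and 3 and with its 3 probes between 0.10 and 2.21. The hormone AMH was at 1.01 ± 0.20 (SD, n = 3). The LH receptor (LHCGR) was at 1.40 ± 1.35 (SD, n = 3), with its other probe at 0.14, and the FSH receptor (FSHR) at 0.10 ± 0.48 (SD, n = 3). The list rose by camera (adjusted p = 0.00948); adjusted p = 0.767 with an estimated correlation, and the alternatives ranged from 2.14e-05 to 0.89. Adjusted over the list alone 0 genes passed, and 0 over all probes. The rise rested on replicate 1: the medians were 0.65, -0.11 and 0.11 in the 3 replicates, and on the slide of replicates 2 and 3 alone the median was 0.02 (adjusted p = 0.464), while without replicate 2 it was 0.32 (2.14e-05). With the slide as a block, where replicate 1 weighed as much as the others together, the median was 0.27. The call was lost with a trend on intensity (adjusted p = 0.12) and over probes detected in all readings (0.161). In the same replicates the leukocyte markers had medians of -2.24, 0.92 and -0.11.

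For steroid synthesis, 15 of 20 measured genes were above 0 and 4 were above 0 in all 3 replicates, while 1 was below 0 in all 3. HSD3B1, which makes progesterone from pregnenolone, had a log2 ratio of 1.65 ± 0.92 (SD, n = 3). CYP11A1, the side-chain cleavage enzyme that makes pregnenolone, stood at 0.63 ± 0.93 (SD, n = 3). STAR, the carrier of cholesterol into mitochondria, had values of -2.79, 2.04 and 1.80 in the 3 replicates, the first of them in the replicate with the lowest leukocyte median (-2.24), and the means of its 3 probes lay between -0.18 and 0.35. The list rose by camera (adjusted p = 0.0409); adjusted p = 0.767 with an estimated correlation, and the alternatives ranged from 0.00979 to 0.767. Over the list alone and over all probes 0 genes passed; CYP19A1 and 2 other genes, HSD17B1 and NR5A2, also belong to the dominant follicle list. On the slide of replicate 1 the median was 0.21, and on that of replicates 2 and 3 it was 0.08 (adjusted p = 0.30). The median was 0.31 with the slide as a block and 0.13 with median centring in place of loess. The call was also lost with a trend on intensity (adjusted p = 0.12), with no filter on dim probes (0.0654) and over probes detected in all readings (0.161).

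The lists closest to the vitamins themselves did not pass the test. Several of their genes were dim, which limits what a ratio near 0 shows. The folate cycle had 13 of 23 measured genes above 0 (median 0.03, mean -0.09 with the test's direction downward, adjusted p = 0.701). MTHFD2, a mitochondrial folate enzyme, was at -0.61 ± 0.61 (SD, n = 3) and detected in 3 of 6 vitamin readings. TYMS, given above, is also a member and had the lowest unadjusted p of this list. It was at -1.03 ± 0.27 (SD, n = 3), with its 3 probes from -1.03 to 0.12. The methionine cycle and transsulfuration list, with 8 of 17 genes above 0, had a median of -0.09 and a mean of 0.00, with the test's direction upward (adjusted p = 0.815). Its methionine synthase (MTR), which needs vitamin B12, was at 0.20 ± 0.23 (SD, n = 3), detected in 5 of 6 readings of each group. The reductase that reactivates it (MTRR) was at -0.12 ± 0.18 (SD, n = 3), detected in 2 of 6 vitamin and 4 of 6 saline readings. AHCYL1 was at 0.84 ± 0.30 (SD, n = 3), with its 3 probes between 0.45 and 0.84. Vitamin B12 uptake and handling had 11 of 15 genes above 0 (median 0.13, adjusted p = 0.38). Within it, ABCD4, a lysosomal carrier of the vitamin, had a ratio of -0.94 where vitamins were in Cy5 and of 1.76 where they were in Cy3; the means of its 4 probes lay between -0.17 and 0.41. DNA methylation and demethylation had 6 of 15 genes above 0 (median -0.15, adjusted p = 0.701). The maintenance methyltransferase DNMT1 was at -0.47 ± 0.95 (SD, n = 3), detected in 4 of 6 vitamin readings. Its partner UHRF1 was at -0.76 ± 0.66 (SD, n = 3). Adjusted over the list alone, 0 genes passed in these 4 lists.

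The response to the LH surge, which starts ovulation, had 19 of 32 measured genes above 0 (median 0.05, adjusted p = 0.446). ADAMTS1, a protease of the ovulating follicle, was at 1.68 ± 0.81 (SD, n = 3) and PLAT, the tissue plasminogen activator, at 1.45 ± 0.69 (SD, n = 3). The progesterone receptor PGR had values of 2.27, -0.87 and -0.65 in the 3 replicates. AREG, an EGF-like ligand, was at 0.06 ± 0.02 (SD, n = 3) and detected in 8 of 12 readings, while none of the 3 probes of PTGS2 was above the negative controls in more than 3 of 12 readings. The cumulus list had 5 of 8 genes above 0 (median 0.54, adjusted p = 0.0879). Its member PTX3, a protein of the expanded cumulus matrix, had the values 5.24, 3.01 and 1.09. Luteinisation and corpus luteum had 14 of 20 genes above 0 (median 0.26, adjusted p = 0.0612). Adjusted over the list alone, AMH passed in the cumulus list and APOA1 in the luteal list. In the LH surge and angiogenesis lists 0 genes passed in that way. Angiogenesis had 7 of 17 genes above 0 (median -0.07, adjusted p = 0.701), and VEGFA stood at -0.07 ± 0.70 (SD, n = 3).

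Several markers of other cell types had opposite signs in different replicates. Of 29 leukocyte markers, 0 of them shared with another list, 23 had a mean below 0 (median -0.31, adjusted p = 0.0612), but the replicate medians were -2.24, 0.92 and -0.11. The list of inflammatory cytokines and chemokines followed them, with medians of -1.35, 0.13 and -0.02 (17 genes, adjusted p = 0.405), and the interferon response had -0.20, 0.51 and -0.01 (18 genes, adjusted p = 0.207). In the epithelial list, 9 of 10 genes were above 0 (median 0.19, adjusted p = 0.40), and KRT8, a keratin of simple epithelia, had the values -0.19, 6.87 and -0.09. Markers of theca and stroma had a median of 0.07 (20 genes, adjusted p = 0.444), of endothelium -0.04 (8 genes, adjusted p = 0.616), of erythrocytes and platelets -0.04 (9 genes, adjusted p = 0.446) and of the oocyte -0.13 (12 genes, adjusted p = 0.314). In these 8 lists 0 genes passed adjusted over the list alone.

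The remaining lists did not pass, and 0 of their genes passed adjusted over the list alone. Cholesterol synthesis and uptake had a median of 0.14 (20 genes, adjusted p = 0.112), with FDPS at 1.00 ± 0.77 (SD, n = 3) and its 4 probes between 0.12 and 1.00. Glycolysis was at -0.13 (20 genes, adjusted p = 0.252), with PGAM1 at -0.79 ± 0.52 (SD, n = 3) and BNIP3 at -0.78 ± 0.49 (SD, n = 3). Insulin and growth factor signalling was at 0.08 (22 genes, adjusted p = 0.494), with IGF2 at 2.41 ± 1.89 (SD, n = 3) and its 3 probes between 0.02 and 2.41; 1 vitamin reading of the printed probe was saturated. TGF-beta family signalling was at 0.12 (27 genes, adjusted p = 0.616), and apoptosis and follicular atresia at 0.04 (21 genes, adjusted p = 0.446). Oxidative phosphorylation had a median of 0.06 (45 genes, adjusted p = 0.571) and fatty acid oxidation and lipid storage of -0.03 (30 genes, adjusted p = 0.813). The heat shock and unfolded protein response stood at -0.08 (25 genes, adjusted p = 0.822) and the immediate early genes at -0.02 (24 genes, adjusted p = 0.857). Antioxidant and glutathione genes had a median of -0.05 and a mean of 0.00 with the test's direction upward (31 genes, adjusted p = 0.857), and GPX1, a glutathione peroxidase, was at 0.94 ± 0.31 (SD, n = 3).

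Among single genes, the 8 with the lowest unadjusted p in each direction are named here as not past the threshold (adjusted p = 0.87 for each). On the higher side were CITED1, a transcriptional co-regulator, at 2.03 ± 0.23 (SD, n = 3), and APOA1, the main protein of high-density lipoprotein, at 2.08 ± 0.39 (SD, n = 3). P3H2, a collagen prolyl hydroxylase, was at 1.75 ± 0.47, GFPT2, an enzyme of hexosamine synthesis, at 1.56 ± 0.44, and lactoferrin (LTF) at 1.42 ± 0.33 (SD, n = 3 each). LOC100296627 was at 1.28 ± 0.11, PLAC9 at 1.25 ± 0.28 and ANTXR2 at 1.10 ± 0.10 (SD, n = 3 each); the 3 probes of ANTXR2 ran from -0.02 to 1.10, the 2 of PLAC9 from 0.62 to 1.25 and the 2 of CITED1 from 1.37 to 2.03. On the lower side, MIS18A, which loads centromeric chromatin, was at -2.19 ± 0.41, TCF19 at -1.71 ± 0.20 and FAM83D, a spindle protein, at -1.68 ± 0.22 (SD, n = 3 each). POLE2, a subunit of DNA polymerase epsilon, was at -1.55 ± 0.10, CENPP, a kinetochore protein, at -1.54 ± 0.17, WDHD1, a replication factor, at -1.46 ± 0.22 and CKAP2, a spindle-associated protein, at -1.46 ± 0.07 (SD, n = 3 each). KIF11, given above, was the other. Of the 3 probes of MIS18A the highest was at 0.10.

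**Figure D2:**
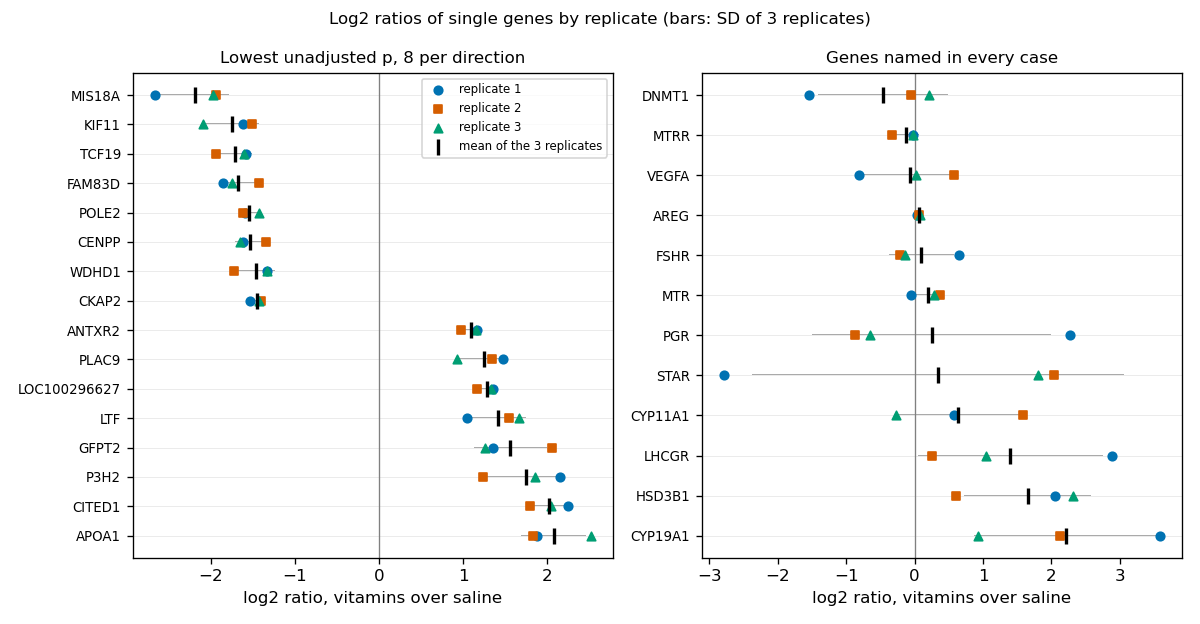
Log2 ratio, vitamins over saline (x axis), of single genes (y axis); circles, squares and triangles are the 3 replicates, the black bar is their mean and the grey line the SD. On the left, the 16 genes of lowest unadjusted p each keep one sign in all 3 replicates, CKAP2 between -1.54 and -1.41; on the right, genes such as STAR, between -2.79 and 2.04, do not.

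Across all 26713 probes, limma called 0 higher and 0 lower at an adjusted p under 0.05, and the lowest adjusted p was 0.87. At an unadjusted p under 0.05 there were 575 higher and 670 lower probes, together 4.66% of those tested. With the 6 arrays in 1 model and duplicateCorrelation for the dye-swap pair the count was also 0, and with the 6 arrays treated as independent, which counts technical arrays as replicates, it was 23 higher and 60 lower. All 3 replicates had 1 sign for 23.6% of the probes, where chance gives 25%.

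The pairs were chosen as the matching with the highest correlation of ratios, so the agreement within pairs and the distance between them follow in part from that choice. Across probes, which are not independent replicates, the correlation of the turned log2 ratios within the pair was r = 0.81 (rho = 0.65) in replicate 1, r = 0.753 (rho = 0.578) in replicate 2 and r = 0.438 (rho = 0.313) in replicate 3. Between arrays of different pairs, r lay between -0.242 and 0.218. Between the replicate ratios, r was -0.192 for replicates 1 and 2, 0.024 for 1 and 3, and 0.12 for 2 and 3. The SD of the log2 ratios over the tested probes was 0.769, 0.59 and 0.413 in replicates 1, 2 and 3.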

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

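The difference between the dye orientations was tested with limma on the half-difference of the 2 arrays of each pair (n = 3), a test chosen after the pairing was known. It flagged 1756 of 26605 probes at an adjusted p under 0.05. The count depends on the inferred pairing, which was chosen for agreement between arrays, and the contrast holds mostly technical spread if that pairing is the true one, so it is not comparable with the count for the treatment. The dye effect cancels in the mean of a pair of opposite orientations. The median absolute effect over all probes was 0.12 log2 units.

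Among the named genes, 6 of 82 differed between orientations. ABCD4 had the largest effect of these, -1.35 (Cy5 over Cy3, log2), and a vitamin ratio of -0.94 with vitamins in Cy5 and 1.76 with vitamins in Cy3. MOS was at -0.77, HSPB1 at -0.60 and RRM2 at -0.42, while S100A9 was at 0.53 and KLF10 at 0.41. For ABCD4 and MOS the sign of the vitamin ratio differed between the orientations; for the other 4 genes it did not, HSPB1 having 0.07 and 1.26.

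Control spots outside the comparison also carried signal, compared with the detection limit set by the negative controls. The median signal of the 320 positive-control spots named E1A was 65.9 times that limit, and that of 36 control spots of a class named DCP was 46.5 times the limit. What these spots were given is not stated in the sources used here, and they were not analysed further.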

How the results depend on the processing

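No alternative turned the direction of a list that passed. Treating the 6 arrays as independent gave 23 higher and 60 lower probes, and 3 of the 5 other pairings of arrays gave 61 and 114, 116 and 163, or 64 and 135; both treat arrays paired here as separate replicates. An unadjusted p under 0.05 with a log2 ratio of at least 0.58 gave 397 higher and 478 lower; every other alternative gave 0. With an estimated correlation all 5 lists that passed had an adjusted p of 0.767. That setting called a simulated shifted list in 0 of 20 draws, so its result does not decide. With fry the adjusted p was 0.371 for the cell cycle, 0.0725 for the extracellular matrix, 0.89 for nucleotide synthesis and the dominant follicle, and 0.513 for steroid synthesis. Leaving out each replicate gave 4.07e-27 to 4.88e-17 for the cell cycle, 0.00388 to 0.00769 for the matrix, 0.000143 to 0.30 for nucleotide synthesis, 2.14e-05 to 0.464 for the dominant follicle and 0.0126 to 0.30 for steroid synthesis. The slide of replicates 2 and 3 alone, the same data as without replicate 1, ended 3 of the calls (0.30, 0.464 and 0.30); the slide of replicate 1 alone gives values but no test. Nucleotide synthesis without the gene shared with the cell cycle list, an alternative chosen after seeing the data, gave 0.0283. That does not separate the list from the cell cycle genes, as TYMS stays in it. Probes detected in all 12 readings gave 0.161 for the dominant follicle and for steroid synthesis, an intensity trend 0.12 for both, and for steroid synthesis no dim filter gave 0.0654 and independent arrays 0.0527. The cause was not tested for these, nor was the smaller number of replicates or probes where some were left out. The replicate block (duplicateCorrelation, consensus 0.705) changed none of the 5 calls; the 0 count stayed. Of lists that had not passed, 30 of 619 values did so in the same direction and 20 moved by over 1 SD; the leukocyte markers ranged from a median of -1.28 without replicate 2 to 0.61 without replicate 1. The dye-swap agreement moved by less than the SD of its 3 values. Of 1861 values of named genes, 57 moved by over 1 SD, and 93 passed the threshold, each with independent arrays or with one of those 3 pairings. Named genes kept their sign in all alternatives except where a replicate or slide was left out or blocked. Signal over background limits dim genes: MTRR and IL6 were detected in 2 of 6 vitamin readings.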

Other observations

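Gene families were picked by name after the data were seen, and members of the fixed cell cycle list were then left out of them. Of 17 centromere genes (CENP) outside that list, 15 had a mean log2 ratio below 0 and 12 were below 0 in all 3 replicates, with replicate medians of -0.52, -0.51 and -0.91; the family's median of -0.77 ran from -0.86 to -0.56 over 22 alternatives. Of 12 MCM, GINS and ORC genes of DNA replication outside the list, 10 were below 0, with a median of -0.31 and a range of -0.41 to -0.26 over the alternatives. Kinesins (KIF) were nearer 0: of 19 outside the list, 11 were below and 8 above 0, 3 of them above 0 in all 3 replicates, with a median of -0.19 and a range of -0.33 to -0.03. The whole families share 2, 6 and 2 members with the list and had medians of -0.79, -0.46 and -0.24. Ribosomal protein genes, 52 of 62 above 0, had replicate medians of -0.16, 0.59 and 0.06, and their median over the alternatives ran from -0.03 to 0.32, so their direction was not kept. Collagen genes as a family (26 measured) had a median of 0.08, keratins (20 measured) of 0.06 and proteasome genes (PSM, 42 measured) of 0.02.

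Some genes, picked after their values were seen, had opposite values of several log2 units in different replicates. VNN1, a member of the LH surge list, had log2 ratios of -5.61, 5.77 and 0.15 in replicates 1, 2 and 3, and the macrophage scavenger receptor CD163 had -5.37, 2.15 and 1.25. FOLR2, a folate receptor of macrophages and a member of the folate cycle list, had -5.56, 2.50 and 0.51. The epithelial genes EPCAM and KRT19 had -3.21, 4.83 and 0.98, and -3.25, 4.43 and 0.97. Other orders were seen as well, with SCG2 at 4.30, 0.59 and -5.27 and GFRA1 at 6.04, -2.27 and -1.11.

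In the next paragraphs the tests on leukocytes, on the share of granulosa cells, on the LH surge and on blood were chosen after the values were seen; the dye, signal level and sign tests were set before their results. The first pattern is the cell cycle list, below 0 in all 3 replicates. A dye bias would give opposite signs in the 2 orientations, but the higher of the 2 orientation medians was -1.05. Leukocytes, which can divide, would as the whole cause lower the list only where leukocyte markers are lower; in replicates 3 and 2, with leukocyte medians of -0.11 and 0.92, the cell cycle medians were -1.29 and -0.53. As part of the cause they stay open: the 2 lists have the same order in 3 of 3 replicates, leukocytes at -2.24, -0.11 and 0.92 and the cell cycle at -1.48, -1.29 and -0.53 in replicates 1, 3 and 2, and 3 replicates are too few to test it. The signal level of the probes is also argued against, since 0% of 10000 random lists matched on mean signal had a median as low, the lowest being at -0.26. A lower rate of division in granulosa cells of treated cows, or follicles at a later stage at collection, may underlie the pattern and stay open, since neither follicle stage nor cow is given per array.

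The second pattern is in replicate 1, where the inhibin subunits and aromatase were far higher with vitamins: INHBB was at 4.36 and CYP19A1 at 3.59. INHA (4.37) and INHBA (3.73) had vitamin readings that were saturated on 1 and 2 of this replicate's arrays, and no saturated saline reading there, so these 2 values are not exact. The lowest of the 4 genes on either array was 2.64, in INHBA, and the lowest of the 2 genes without saturated readings was 3.47. A dye bias would give opposite signs on the 2 arrays, and the lowest value of 2.64 on either array argues against it. Fewer granulosa cells in the saline sample cannot be told apart from a vitamin effect. The other 21 genes of the list had a median of 0.49 but ran from -0.48 to 2.89. The 4 genes had been picked as the highest of the list, so a lower median of the rest decides nothing. A saline sample collected later after the LH surge, when these genes fall, could not be told apart from a vitamin effect: the LH surge list had a median of 0.05 in that replicate, with TNFAIP6 at 6.54 and MMP19 at -4.21. A difference between the follicles of that pair, which the labels do not describe, may be the source.

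The third pattern is the leukocyte markers, with medians of -2.24 in replicate 1 and 0.92 in replicate 2. All 4 arrays kept the sign of their replicate, the smallest absolute median being 0.97, against a dye bias. Of the markers with a high mean signal, BOLA-DRA had -4.33 and 3.36, C1QB -3.99 and 3.30, and RAC2 -3.70 and 3.30 in these replicates, while GZMB had 1.70 and -0.33. Granulosa cells had been picked under a stereomicroscope, per the labels. Blood in the aspirates cannot be told apart from tissue macrophages as a candidate source, since 1 well-detected gene of red cells or platelets was measured. With opposite signs in these replicates, 3 ratios cannot separate a treatment effect from differences between the samples. The list did not pass camera with a preset correlation (adjusted p = 0.0612).

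Turning the sign of whole replicates gives 4 assignments of the 3 replicates, too few for a share under 0.05. The labelled assignment gave 1245 probes at an unadjusted p under 0.05 and the highest of the others 1790, so 2 of 4 gave as many. It gave 5 lists past the threshold and the highest of the others 8, again 2 of 4. The assignment with 1790 probes turned replicate 1, the replicate on its own slide, so slide and replicate cannot be separated there. The one with 8 lists turned replicate 2, and its leukocyte list reached an adjusted p of 1.08e-10, so differences between the replicates' samples can pass camera with a preset correlation. The cell cycle list had an adjusted p of 6.2e-26 as labelled and 2.95e-06, 0.173 and 0.306 in the others.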
